A study of Arabidopsis thaliana with 4 samples.

How the data were processed

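The data are 4 RNA-seq libraries of Arabidopsis thaliana Col-0, 2 of whole leaf and 2 of leaf protoplasts. Per the labels' protocols, plants grew for 6 weeks in 8 h light and 16 h dark at 60 µmol photons per square metre and second. Per the labels' protocols, protoplasts were released in 2 h by 1% cellulase and 0.3% macerozyme in 0.6 M mannitol, then filtered and washed, and poly(A) RNA of both kinds was made into libraries with a directional kit and sequenced as read pairs. Leaf was not exposed to the enzymes or mannitol, so the comparison covers all steps of the isolation at once. The hours at which leaves and protoplasts were collected are not given in the sources used here.

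The deposited count table holds whole-number read counts per gene locus, with 1 column per library and no normalization. STAR and DESeq are named, without versions, in the submitters' processing notes; the genome build, annotation, counter and strand setting are not given in the sources used here. Every row of the deposited counts sums to at least 2, so loci with fewer counts were left out beforehand. The authors' comparison table holds, per the file headers, a mean normalized count per gene, here treated as a signal of the authors without error, the log2 fold change with its standard error, a test statistic, which is a score by the authors, and a p-value with its adjusted p-value. A DESeq2 run here on the deposited counts without a filter gave the same log2 fold changes to within 6.52e-09 and the same number of adjusted p-values under 0.05, 14834. The comparison table serves only for the comparison with the calls made here.

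The count table has 24904 loci, of which 24651 were matched by locus tag to NCBI's gene table of assembly TAIR10.1, and the 253 unmatched loci are all chloroplast or mitochondrial. That table gave names and neighbouring genes only. No coordinates are given, since the build of the counts is not given in the sources used here. Because the strand setting is not known, counts of overlapping and antisense genes are uncertain, as are those of near-identical copies. The loci ATCG00950 and ATCG01180, copies of the same ribosomal RNA, have counts within 0.0862% of each other.

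Total counts were 42121436 and 43685947 for leaf and 48503141 and 39958035 for protoplasts. A count of 0 was treated as at most 3 counts per library, and folds against such a group are lower bounds. Genes with 1 to 3 counts in a group have their ratio given with an exact 95% interval. Intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

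Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with group as the only term, TMM factors (1.323 and 1.321 for leaf, 0.764 and 0.749 for protoplasts) and the filterByExpr filter, which left 20200 genes and set aside 4704. P-values were adjusted by Benjamini and Hochberg's method with a threshold of 0.05, and the common biological coefficient of variation was 0.0486. Fold changes are protoplast minus leaf on the log2 scale, and their SE is the size of the fold change divided by the square root of F. CPM values use the TMM-scaled library sizes and are given as mean ± SD over 2 libraries. As nothing in the labels names separate plants or days, p-values measure only the spread between these libraries, which may be technical.

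The 27 gene lists, 7 of cell types and 20 of pathways, the alternatives and the rule for named genes were fixed before the data were examined. The cell type lists are companion cell and sieve element, phloem parenchyma transporters, xylem and secondary wall, bundle sheath, epidermis and cuticle, guard cell, and trichome. Of 469 listed members, 452 carry the listed symbol in the reference, 12 have no symbol there and are shown by locus, 4 are the same gene under another symbol, and 1 was left out as another gene; 5 have no row in the count table. Each list was tested with camera of limma 3.58.1, with a preset correlation of 0.01 between genes, and adjusted over the lists. With 2 residual degrees of freedom, 0 of the 27 lists were called with an estimated correlation (6 had an unadjusted p under 0.05), against 17 with the preset one; fry, which asks whether the genes of a list move on balance one way, called 27.

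The named genes are of 3 kinds. They are, among genes with an adjusted p under 0.05, at least 10 CPM in one group, no overlap of libraries and a symbol, the 12 with the largest and the 12 with the smallest log2 fold change. They are also, from each list, the 2 called members at each end, or where none is called the member with the highest mean count. Last, they are any measured member of the companion cell and sieve element, phloem parenchyma transporter and reference gene lists. A listed locus whose reference symbols lack the listed one was shown under the reference's symbol where it is the same gene, and otherwise left out. The text prints only some of the genes this rule gives, and 1 of them is not reported here. The morning and evening clock genes beyond this rule were named in a test written before their values were seen.

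The analysis was tested on simulated data drawn from the real leaf means and library sizes, with 200 of 18938 genes changed. Of genes changed 2-fold it recovered 83.5% and of genes changed 4-fold 98.8%, and 2.65% of its calls were unchanged genes. With so few genes changed, these rates do not carry over to the real comparison, where 80.5% of tested genes were called. Alternatives were RLE and upper-quartile factors, library size only, DESeq2 1.42.0, limma-voom, other filters, a replicate block, leaving out each library, leaving out organelle loci, and, chosen after seeing the data, scaling to the 11 reference genes and to the 10 other than UBQ10. Tables were joined and figures drawn in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.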

Results

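Poly(A) RNA was sequenced from mature leaves of Arabidopsis thaliana, accession Col-0, and from protoplasts of such leaves. The plants were 6 weeks old and had grown in short days of 8 h light and 16 h dark. For the protoplasts, the lower epidermis was stripped off with tape and the rest of the leaf was digested for 2 h in a solution of cell wall enzymes and 0.6 M mannitol, by the method the study used for single-cell sequencing. Whole leaf and leaf protoplasts each had 2 libraries, which the labels call biological replicates without naming plants or days. The leaf libraries held 42121436 and 43685947 counts and the protoplast libraries 48503141 and 39958035. Chloroplast loci took 3.94% and 3.51% of the leaf counts and 4.50% and 5.95% of the protoplast counts. Across the tested genes, which are not independent replicates, log-scale CPM correlated with r = 0.996 between the leaf libraries, 0.994 between the protoplast libraries and 0.724 to 0.726 between a leaf and a protoplast library. Both pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 5.2 for leaf and 10.4 for protoplasts.

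The design holds a single comparison, which asks how the transcripts of leaf protoplasts differ from those of the intact leaf. Most genes on the lists of jasmonate and wounding and of early stress transcription factors and calcium rose in protoplasts (27 of 31 and 24 of 25), while most on those of epidermis, guard cell and aliphatic glucosinolate fell (23 of 24, 14 of 15 and 12 of 12). As sets these lists were called by camera with a preset correlation only (adjusted p = 0.166 to 0.207 with an estimated correlation). Of 20200 genes tested, 8036 rose and 8231 fell (edgeR quasi-likelihood test, adjusted p under 0.05), and 4473 rose and 3980 fell at least 2-fold. The 1610 genes that rose at least 16-fold took 0.768% and 0.772% of the counts in leaf and 20.5% and 20.1% in protoplasts. The genes that fell at least 2-fold took 10.9% of the counts in each leaf library and 1.46% and 1.44% in the protoplast libraries. The libraries of the groups did not overlap for 18241 genes, or 90.3% of those tested, where chance gives 33.3%. The split between rising and falling genes depended on the scaling. Of the calls, 49.4% were higher with TMM factors, 51.2% with RLE factors, 50.1% with scaling to 10 reference genes without UBQ10, 40.3% with scaling to these and UBQ10, 35.9% with upper-quartile factors and 23.5% with library size only. The median log2 fold change of all genes was, in the same order, -0.04, -0.01, -0.03, -0.25, -0.37 and -0.85, and the fold changes below are relative to that of -0.04. Of 27 gene lists, camera called 9 higher and 8 lower with a preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.166 and 6 lists had an unadjusted p under 0.05. With 2 libraries against 2, an exact permutation test of a single gene cannot give a p below 0.333, so the calls rest on the spread pooled over genes.

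**Figure D1:**
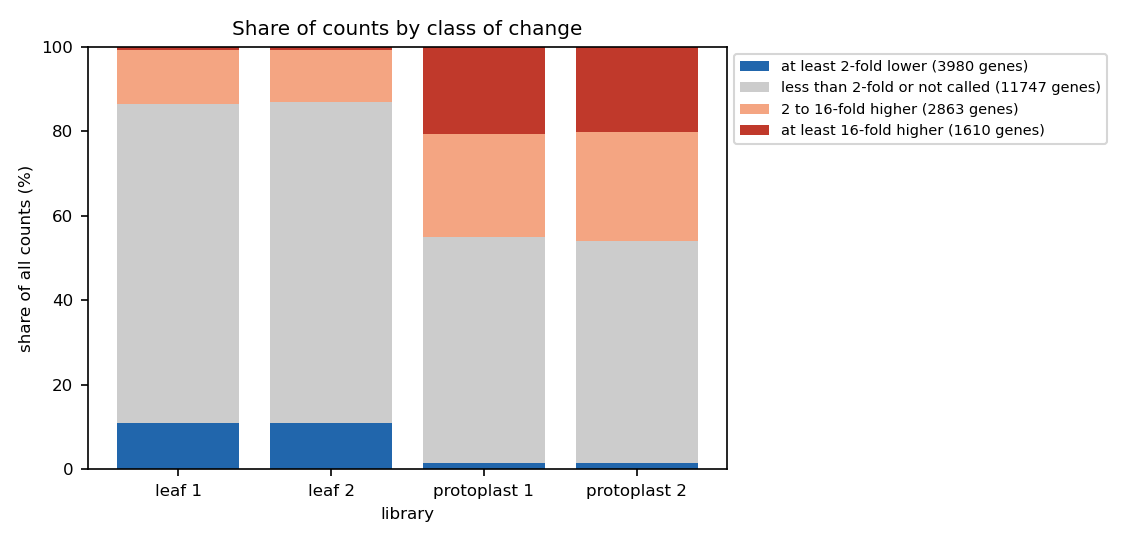
Share of all counts, in percent, taken in each of the 4 libraries by genes grouped by their change in protoplasts against leaf. The genes at least 16-fold higher took under 1% of the counts in either leaf library and 20.5% and 20.1% in the protoplast libraries.

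Most markers of the epidermis, guard cells and vascular cells were lower in protoplasts. Of 24 tested genes of epidermis and cuticle, 23 fell and 1 rose. CUT1, which elongates fatty acids for cuticular wax, fell from 350.5 ± 12.1 to 0.633 ± 0.328 CPM (mean ± SD, n = 2), a log2 fold change of -9.05 ± 0.12 (SE). FDH, of the same enzyme family, fell by 8.62 ± 0.10 on the log2 scale, and CER4, with 0 protoplast counts, was at least 48.4-fold lower. The list's median log2 fold change was -5.73, or -5.56 with 2 genes at their bounds (camera, adjusted p = 4.16e-25; adjusted p = 0.207 with an estimated correlation). DCR, an acyltransferase of cutin synthesis, rose from 0.618 ± 0.090 to 1.35 ± 0.11 CPM (n = 2), a call that ended with library size only (adjusted p = 0.237). Among 15 guard cell genes 14 fell and 1 rose, with a median of -4.89 (adjusted p = 2.93e-06; adjusted p = 0.194 with an estimated correlation). ALMT12, an anion channel of guard cells, was at least 63.6-fold lower with 0 protoplast counts, and MYB60, with 3 protoplast counts, was 114-fold lower with a 95% counting interval of 38.9 to 556. TGG1, a myrosinase, had 790.4 ± 40.2 CPM in leaf and 922.5 ± 43.9 CPM in protoplasts (n = 2), a log2 fold change of 0.22 that turned to -0.58 with library size only and -0.10 with upper-quartile factors.

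Vascular markers fell as well. Of 20 tested genes of companion cells and sieve elements, 17 fell and 0 rose, with a median log2 fold change of -3.54 (adjusted p = 1.49e-11; adjusted p = 0.207 with an estimated correlation). SUC2, which loads sucrose into the phloem, fell from 169.5 ± 6.1 to 6.30 ± 0.21 CPM (n = 2), and PP2-A1, a lectin of the phloem, fell from 224.4 ± 6.8 to 2.76 ± 0.45 CPM (n = 2). OPT3 fell least among the called members, by 1.32 ± 0.06 on the log2 scale, and NAC045, NAC086 and NEN4, each under 0.3 CPM in leaf, were not past the threshold. NAC045, with a log2 fold change of -1.11 ± 0.57, passed it with upper-quartile factors and library size only (adjusted p = 0.0303 and 0.0049). It also passed with scaling to the 11 reference genes (adjusted p = 0.0462). All 11 tested transporters of phloem parenchyma fell, with a median of -5.33 (adjusted p = 5.47e-13; adjusted p = 0.195 with an estimated correlation). The sucrose exporters SWEET11 and SWEET12 had log2 fold changes of -4.35 ± 0.06 and -4.47 ± 0.11, and the amino acid exporter UMAMIT17 fell by 5.57 ± 0.10. Of 23 xylem and secondary wall genes 19 fell and 1 rose over all genes, and 20 fell and 1 rose adjusted over the list alone. Their median was -5.02, or -4.01 with 3 genes at their bounds (adjusted p = 4.17e-05; adjusted p = 0.379 with an estimated correlation). PHO1, a phosphate exporter of the stele, fell from 35.2 ± 2.0 CPM to a total of 2 counts, a 1180-fold difference with a counting interval of 326 to 9750. MYB83, the xylem regulator that rose, had 8 and 11 counts in leaf and 14 and 16 in protoplasts, and its call ended with library size only (adjusted p = 0.198), with DESeq2 (adjusted p = 0.0842), without leaf replicate 1 (adjusted p = 0.083) and without protoplast replicate 2 (adjusted p = 0.106).

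The remaining marker lists were not called as sets. All 5 tested bundle sheath genes fell, among them JKD and MYB76, with a median of -1.67 (adjusted p = 0.0847). The set was called without leaf replicate 1 (adjusted p = 0.0447) and without protoplast replicate 1 or 2 (adjusted p = 0.0148 for each). Of 6 trichome genes, 4 fell and 2 rose (median -1.88, adjusted p = 0.563). GL2 was 64.3-fold lower with a counting interval of 11.3 to 2560, and MYB23 was at least 9.33-fold lower. GL1 rose from 0 counts in both leaf libraries to 32 and 30 counts in the protoplast libraries. TRY rose by 0.51 ± 0.09 on the log2 scale, which turned to -0.29 with library size only and was not past the threshold with upper-quartile factors (adjusted p = 0.0674). Adjusted over the list alone, the numbers of rising and falling members equalled those over all genes for every list except xylem and light harvesting, for which both are given.

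**Figure D2:**
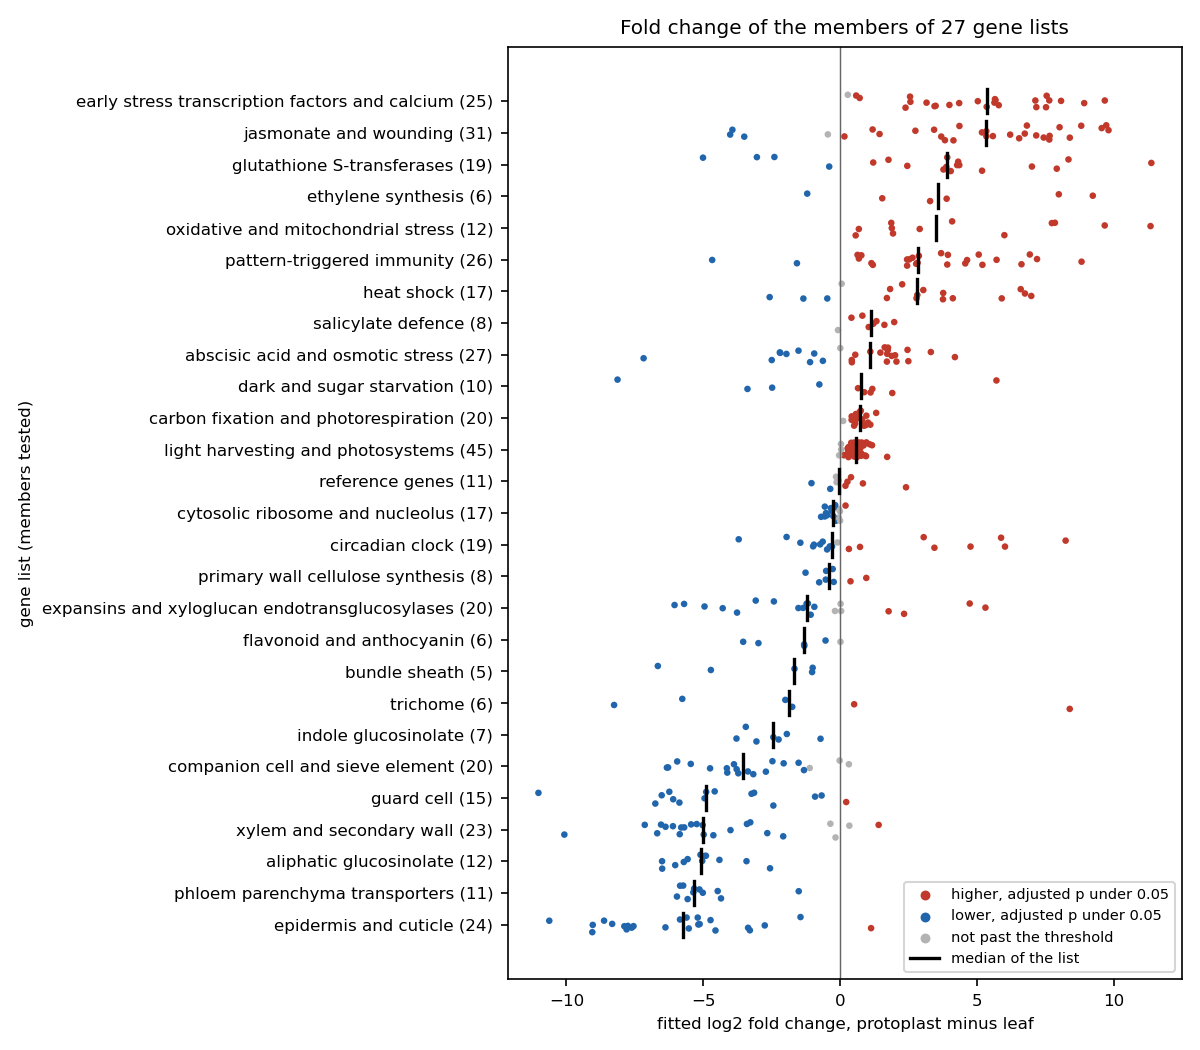
Fitted log2 fold change of protoplast minus leaf for each tested member of 27 gene lists, ordered by the list's median, with 2 libraries per group, each point being a gene and each vertical bar a median; fitted values of genes with 0 counts in a group depend on the prior count. The epidermis list has the lowest median, -5.73, and the lists of early stress transcription factors and calcium (5.36, or 5.03 with 1 gene at its bound) and of jasmonate and wounding (5.34) the highest, while the medians of both photosynthesis lists turned to -0.24 and -0.07 with library size only.

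Photosynthesis genes were moderately higher with TMM scaling. Of 45 genes of light harvesting and the photosystems, 41 rose and 0 fell over all genes, and 42 rose adjusted over the list alone, with a median of 0.56 (adjusted p = 0.0283; adjusted p = 0.207 with an estimated correlation). LHCB4.3, an antenna protein of photosystem II, rose from 42.6 ± 2.1 to 140.3 ± 6.2 CPM (n = 2). Of 20 genes of carbon fixation and photorespiration, 19 rose and 0 fell, with a median of 0.74 (adjusted p = 0.0249; adjusted p = 0.207 with an estimated correlation). SHM1, a serine hydroxymethyltransferase of photorespiration, rose from 1319 ± 48 to 3290 ± 253 CPM (n = 2), and CA1, a carbonic anhydrase, from 2416 ± 158 to 5197 ± 155 CPM (n = 2). These rises moved beside the fall of the epidermis list (median -5.73) and of the phloem parenchyma list (median -5.33). Both photosynthesis calls ended with upper-quartile factors (adjusted p = 0.13 and 0.0914), and with library size only the medians turned to -0.24 and -0.07. They also ended with scaling to all 11 reference genes (adjusted p = 0.0886 and 0.0578) and stayed when UBQ10 was left out of these (adjusted p = 0.0272 and 0.0235). The LHCB1 and RBCS genes are near-identical copies, so the counts of single members are uncertain.

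Genes of jasmonate synthesis and signalling rose in protoplasts. Of 31 tested members of the jasmonate and wounding list 27 rose and 3 fell, with a median of 5.34 (adjusted p = 1.53e-42; adjusted p = 0.194 with an estimated correlation). With library size only, 26 were called higher. JAZ10, a repressor of jasmonate signalling, rose from 0.249 ± 0.181 to 223.8 ± 15.1 CPM (n = 2), a log2 fold change of 9.81 ± 0.15. AOC3, an allene oxide cyclase, rose from 1.398 ± 0.277 to 1189 ± 48 CPM (n = 2), and its similarity to AOC1 and AOC2 leaves the division of counts among them uncertain. The members that fell were AOC4, VSP1 and JMT, respectively a cyclase of jasmonate synthesis, a vegetative storage protein and a methyltransferase of jasmonate. JMT was named after its value was seen. The jasmonate genes rose in the libraries in which the companion cell list (median -3.54) and the guard cell list (median -4.89) fell.

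Early regulators of stress responses rose as a group. Of 25 stress transcription factors and calcium sensors, 24 rose and 0 fell, with a median of 5.36, or 5.03 with 1 gene at its bound (adjusted p = 2.29e-35; adjusted p = 0.166 with an estimated correlation). With library size only, 22 were called higher. CML37, a calmodulin-like protein, rose from 2.29 ± 0.27 to 1873 ± 111 CPM (n = 2). In the list of pattern-triggered immunity 24 of 26 genes rose and 2 fell, with a median of 2.86 (adjusted p = 7.24e-16; adjusted p = 0.194 with an estimated correlation). Of these genes, 21 were called higher with library size only. PUB22, a ubiquitin ligase, rose from 0.891 ± 0.034 to 131.0 ± 1.4 CPM (n = 2), while PROPEP1, a peptide precursor, and PGIP2, an inhibitor of polygalacturonase, fell. Of 6 ethylene synthesis genes, 5 rose and 1 fell, with a median of 3.59 (adjusted p = 7e-05; adjusted p = 0.195 with an estimated correlation). The synthase genes ACS8 and ACS2 rose by 9.23 ± 0.12 and 7.99 ± 0.13 on the log2 scale. The salicylate defence list had 7 of 8 members that rose and 0 that fell, among them PAD4, from 7.16 ± 0.02 to 28.2 ± 0.5 CPM (n = 2), but was not called as a set (median 1.13, adjusted p = 0.0812). The set was called without protoplast replicate 1 (adjusted p = 0.00813) and without protoplast replicate 2 (adjusted p = 0.00855). Across these stress lists, the xylem list (median -5.02) and the epidermis list (median -5.73) fell in the same libraries.

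All 12 tested genes of oxidative and mitochondrial stress rose, with a median of 3.50 (adjusted p = 8.61e-13; adjusted p = 0.194 with an estimated correlation). With library size only, 10 of them were called higher. UGT74E2, a glycosyltransferase of indole-3-butyric acid, rose from 0.0885 ± 0.0271 to 236.3 ± 10.8 CPM (n = 2), and OXI1, a kinase of oxidative signalling, from 0.337 ± 0.133 to 275.4 ± 15.1 CPM (n = 2). Of 19 glutathione S-transferases 15 rose and 4 fell, with a median of 3.92 (adjusted p = 2.82e-09; adjusted p = 0.194 with an estimated correlation). GSTU3, with 1 count in leaf, was 3490-fold higher with a counting interval of 626 to 138000, and GSTU20 fell from 121.6 ± 0.5 to 3.81 ± 0.61 CPM (n = 2). GSTU3 lies among similar GSTU copies, so its counts are uncertain. Of 17 heat shock genes 13 rose and 3 fell, with a median of 2.82 (adjusted p = 1.84e-06; adjusted p = 0.207 with an estimated correlation). DREB2A, a regulator of drought and heat responses, rose from 5.28 ± 0.39 to 571.7 ± 32.4 CPM (n = 2), while HSFA7A fell by 2.57 ± 0.22 on the log2 scale. The abscisic acid and osmotic stress list went both ways, with 17 of 27 members higher and 9 lower (median 1.104, adjusted p = 0.45). RD26, a NAC transcription factor, rose from 45.9 ± 0.5 to 841.4 ± 22.6 CPM (n = 2), whereas RD22, a dehydration-responsive gene, fell from 1016 ± 9 to 7.01 ± 0.02 CPM (n = 2). The epidermis list (median -5.73) and the phloem parenchyma list (median -5.33) fell in these libraries.

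Glucosinolate synthesis genes fell. All 12 genes of the aliphatic branch fell, with a median of -5.07 (adjusted p = 3.5e-22; adjusted p = 0.195 with an estimated correlation). MAM3, a chain-elongation enzyme, fell from 77.7 ± 1.1 to 0.863 ± 0.151 CPM (n = 2), and CYP79F1, which starts the core pathway, from 174.6 ± 7.1 to 1.91 ± 0.20 CPM (n = 2), with counts that may be shared with its close copy CYP79F2. All 7 genes of the indole branch fell, with a median of -2.44 (adjusted p = 1.84e-06; adjusted p = 0.207 with an estimated correlation), among them CYP79B2, by 3.79 ± 0.08 on the log2 scale. Of 6 flavonoid genes, 5 fell and 0 rose, without a call of the set (median -1.31, adjusted p = 0.128), and CHI, chalcone isomerase, fell by 3.54 ± 0.16. The flavonoid set was called without protoplast replicate 1 (adjusted p = 0.0471) and without protoplast replicate 2 (adjusted p = 0.034). In the list of expansins and xyloglucan endotransglucosylases, 13 of 20 genes fell and 4 rose (median -1.2, adjusted p = 0.0356; adjusted p = 0.22 with an estimated correlation). The expansin EXPA5 fell by 6.05 ± 0.13 on the log2 scale, and the touch-induced TCH4 rose from 26.9 ± 1.1 to 1069 ± 82 CPM (n = 2). These falls stood beside those of the phloem parenchyma (median -5.33), bundle sheath (median -1.67) and epidermis (median -5.73) markers.

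Primary wall and ribosome genes were not called as sets with TMM factors. Of 8 genes of primary wall cellulose synthesis, 6 fell and 2 rose (median -0.39, adjusted p = 0.253). COB fell by 1.26 ± 0.05 on the log2 scale, and CESA6 rose by 0.38 ± 0.05, which turned to -0.43 with library size only and was not past the threshold with upper-quartile factors (adjusted p = 0.319). The wall set was called with library size only (median -1.195, adjusted p = 0.0491). Of 17 genes of the cytosolic ribosome and nucleolus, 12 fell and 1 rose (median -0.25, adjusted p = 0.174), and this set was called without protoplast replicate 2 (adjusted p = 0.0164) and with library size only (median -1.057, adjusted p = 0.0215), limma-voom (adjusted p = 0.0188) and no filter (adjusted p = 0.00715). The gene that rose, NUC1, a nucleolin, had 99.1 ± 2.4 CPM in leaf and 113.8 ± 5.4 CPM in protoplasts (n = 2), and its log2 fold change of 0.20 turned to -0.61 with library size only and -0.13 with upper-quartile factors.

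Clock genes fell into opposite directions. Of 19 tested members 8 rose and 10 fell, so that the list's median was -0.29 and its mean 1.095, and camera, whose direction was up, did not call it (adjusted p = 0.801). PRR5 rose from 0.256 ± 0.044 to 78.2 ± 2.6 CPM (n = 2), a log2 fold change of 8.24 ± 0.11. The evening genes TOC1, LUX and ELF4 rose by 4.77 ± 0.07, 3.45 ± 0.11 and 3.05 ± 0.35 on the log2 scale. GI, also of the evening, rose by 0.32 ± 0.11, which turned to -0.01 with upper-quartile factors and -0.48 with library size only. The morning genes CCA1 and LHY had 901.3 ± 49.7 and 929.0 ± 23.1 CPM in leaf and 580.1 ± 24.0 and 715.7 ± 0.3 CPM in protoplasts (n = 2), and fell together with PRR9 and RVE8. RVE1 fell by 1.95 ± 0.07 on the log2 scale. In the list of dark and sugar starvation 6 of 10 genes rose and 4 fell. Its median of 0.77 and mean of -0.33 differed in sign, and it was not called (adjusted p = 0.166). TPS11, of the trehalose phosphate synthase family, rose from 14.03 ± 0.16 to 736.0 ± 6.8 CPM (n = 2). The epidermis markers (median -5.73) and the vascular markers of the companion cell list (median -3.54) fell in the same libraries.

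**Figure D3:**
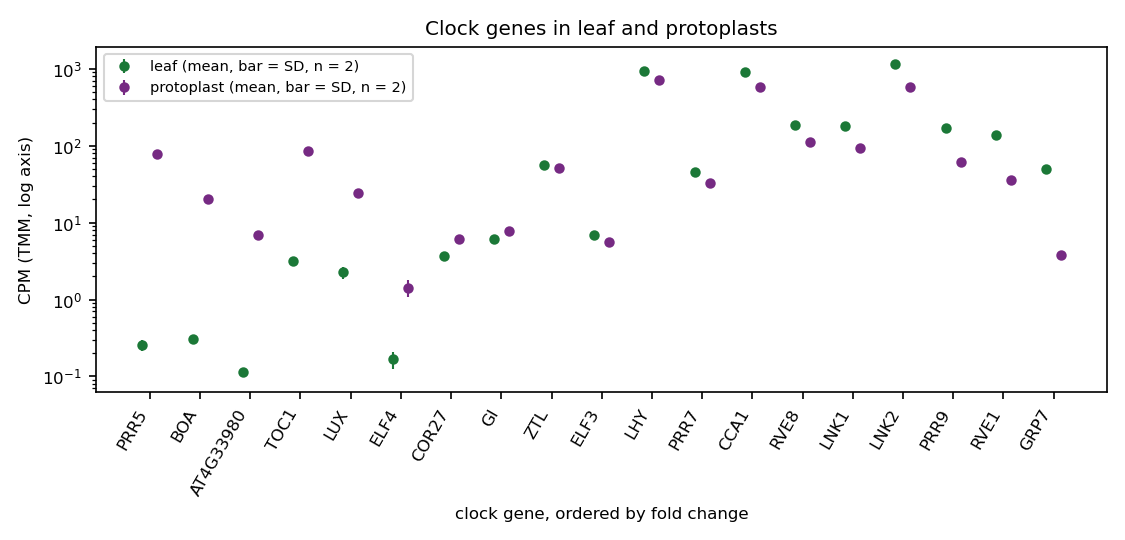
CPM with TMM factors, on a log axis, of 19 clock genes in leaf and in protoplasts, as mean and SD of 2 libraries, ordered by fold change. PRR5 was at 0.256 CPM in leaf and 78.2 CPM in protoplasts, while CCA1 was at 901.3 and 580.1 CPM, and the rise of GI turned to -0.48 and that of COR27 to -0.08 with library size only.

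Genes often used as references were not level. Of 11 tested, 5 rose, 2 fell and 4 were not past the threshold (median -0.06, mean 0.21, adjusted p = 0.874). UBQ10 rose from 1141 ± 9 to 6062 ± 89 CPM (n = 2), and ACT7 fell from 173.2 ± 1.1 to 84.0 ± 3.3 CPM (n = 2), both with the same sign under every scaling tried. ACT2, PP2AA3 and the TIP41-like gene AT4G34270 rose by 0.27 ± 0.05, 0.40 ± 0.06 and 0.20 ± 0.08 on the log2 scale, and turned to -0.54, -0.41 and -0.61 with library size only. With upper-quartile factors ACT2 turned to -0.06 and AT4G34270 to -0.13, and PP2AA3 was not past the threshold (adjusted p = 0.27). Scaling to the 11 reference genes ended the calls of ACT2 and AT4G34270 (adjusted p = 0.21 and 0.917). The call of AT4G34270 also ended without leaf replicate 2 (adjusted p = 0.269), without protoplast replicate 2 (adjusted p = 0.268), with the replicate block (adjusted p = 0.0688), with DESeq2 (adjusted p = 0.0601), with limma-voom (adjusted p = 0.0527) and without a filter (adjusted p = 0.0803). The genes not past the threshold, AT2G28390, AT5G60390, UBC21 and YLS8, were called lower with upper-quartile factors and library size only. Their log2 fold changes with library size only were -0.93, -0.90, -0.95 and -0.86. They were also called lower with scaling to the 11 reference genes, to which they belong (adjusted p = 0.00109, 7.23e-05, 0.00547 and 8e-04). AT2G28390 was also called lower without leaf replicate 1 (adjusted p = 0.037), UBC21 without protoplast replicate 1 (adjusted p = 0.0202), and AT5G60390 with limma-voom (adjusted p = 0.0352) and without a filter (adjusted p = 0.026).

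Among genes with a symbol, at least 10 CPM in a group and no overlap of libraries, the largest rise by fitted fold was that of MYB108, a transcription factor with 3 leaf counts in all and 434.3 ± 22.4 CPM in protoplasts (n = 2), a ratio of 16500 with a counting interval of 5640 to 79900. The kinase gene MAPKKK21 rose from 0.167 ± 0.008 to 837.7 ± 66.9 CPM (n = 2), and ABR1, an ERF-family regulator, from 0.219 ± 0.132 to 1044 ± 6 CPM (n = 2). GulLO1, WRKY67 and UGT73B4, each with 0 leaf counts, were at least 764-fold, 323-fold and 249-fold higher. At the other end, EXPA16, an expansin with 0 protoplast counts, was at least 185-fold lower. KCS3, related to the fatty acid elongases of wax synthesis, fell from 115.9 ± 1.8 to 0.131 ± 0.044 CPM (n = 2). In all, 404 tested genes had 0 leaf counts and were called higher, and 238 had 0 protoplast counts and were called lower. Such genes pass the filter only through the other group, so their direction was fixed in advance.

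The authors' deposited table gives 14834 genes with an adjusted p under 0.05, 8142 higher and 6692 lower in protoplasts. Of the 16267 genes called here, 14035 are also called in the authors' deposited table with the same sign and 0 with the opposite sign, and 2232 are called here only. The authors' deposited table also calls 798 genes that the filter on low counts kept out of the test here, and 1 gene that was tested and not called. Across tested genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and those fitted here correlated with r = 0.999.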

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

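Scaling to the 11 reference genes, and to the 10 other than UBQ10, was chosen after seeing the data; the other alternatives were planned. With library size only, 4326 genes were higher and 14057 lower, and the number of genes at least 2-fold lower in protoplasts was 8822, against 8036, 8231 and 3980 with TMM; this setting leaves out the composition factors by construction. Under every other alternative run these counts, and that at least 2-fold higher, stayed within 1.5 times. Leaving out 1 library gave 7537 to 7957 genes higher and 7700 to 7928 lower, where the lone library of a group is assumed to vary like the other group, and 17 to 21 lists called. With camera at an estimated correlation 0 lists were called (adjusted p 0.166 to 0.883) and with fry 27, against 17.

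With library size only the median log2 fold changes turned to -0.2407 for light harvesting and -0.06895 for carbon fixation, and the fold changes of TGG1 to -0.5822, TRY to -0.2915, CESA6 to -0.4254, NUC1 to -0.6071, ACT2 to -0.5375, PP2AA3 to -0.4064 and AT4G34270 to -0.6096. With upper-quartile factors TGG1 turned to -0.1043, NUC1 to -0.1286, ACT2 to -0.05916 and AT4G34270 to -0.1314. With the 11 reference genes, of which AT4G34270 is 1, NUC1 turned to -0.006441 and AT4G34270 to -0.009465. Without UBQ10 among them no sign and no call of a list or named gene changed, so the changes with the 11 genes rest on UBQ10. All genes shift together under a scaling by construction; beyond this, the cause was not tested. With the preset correlation, the list calls lost were those of both photosynthesis lists under upper-quartile factors, library size only and the 11 reference genes. Bundle sheath, salicylate defence, ribosome and flavonoid lists gained a call with limma-voom and without a filter. With at least 1 CPM in 2 libraries, 26 of the 27 lists had enough members. DESeq2 was not run for the lists, as camera does not take it.

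With a replicate block 7782 genes were higher and 7868 lower. The labels do not say whether replicate numbers pair the libraries. Differences between replicates 1 and 2 correlated across 20200 genes with r = -0.0814 (Spearman -0.151), which cannot settle it. The block ended the call of AT4G34270 and no other call of a list or named gene. A count of 0 allows up to 3 counts, or 0.0619 to 0.0751 CPM by library size, and lower levels were not detectable.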

Other observations

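Gene families, grouped by the letters that open their symbols, were tested after the lists' results were seen, with 126 families of at least 10 tested members. Camera called 17, 11 higher and 6 lower, and with an estimated correlation 0 were called, with an adjusted p of 0.823 or more for those 17. Mitogen-activated kinase kinase kinases (MAPKKK) had 7 of 12 members higher and 2 lower, with a median log2 fold change of 4.12 (adjusted p = 5.43e-09; adjusted p = 0.823 with an estimated correlation). Glycosyltransferases named UGT had 26 of 45 higher and 13 lower (median 1.42, adjusted p = 0.000718; adjusted p = 0.823 with an estimated correlation). Transporters named UMAMIT, some of which are also in the phloem parenchyma list, had 26 of 30 lower and 3 higher (median -1.77, adjusted p = 5.71e-06; adjusted p = 0.946 with an estimated correlation). Serine carboxypeptidase-like genes (SCPL) had 22 of 27 lower (median -1.43, adjusted p = 0.00775; adjusted p = 0.823 with an estimated correlation) and beta-glucosidases (BGLU) 20 of 24 (median -1.35, adjusted p = 0.0127; adjusted p = 0.916 with an estimated correlation). These 5 medians kept their sign under every scaling tried. Of the other called families, EXO, HSP and NAC had medians of 0.57, 0.61 and 0.05 that turned to -0.24, -0.20 and -0.75 with library size only, and that of NAC was -0.28 with upper-quartile factors and -0.15 with scaling to the 11 reference genes (0.07 without UBQ10 among them).

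Noncoding and organellar loci went both ways, and no class was tested against coding genes. The libraries were made from poly(A) RNA, so for RNA without a poly(A) tail these counts need not follow abundance. Of 22 tested loci that the reference types as antisense RNA, 20 were higher and 1 lower, with a median of 6.60, or 3.71 with the 9 loci that had 0 leaf counts at their bounds, at a median of 0.832 CPM in protoplasts. Those 9 passed the filter only through the protoplast libraries, which fixed their direction. For 21 of the 22 antisense loci a tested coding gene lies on the other strand, and these partners had a median of -0.14. Of 14 pairs with both called, 6 went the same way. As the strand setting of the counts is not given in the sources used here, reads of such a locus and of its partner cannot be separated. Of 493 loci typed as long noncoding RNA, 284 were higher and 128 lower, with a median of 1.37. Among these, 73 had 0 leaf counts and 8 had 0 protoplast counts. Of 114 chloroplast loci 94 were higher and 6 lower, with a median of 1.17. Of 62 mitochondrial loci 23 were higher and 11 lower, with a median of 0.28 that turned to -0.05 with upper-quartile factors and -0.52 with library size only. All 3 ribosomal RNA loci and all 3 small nuclear RNA loci tested were higher. The latter had 0 leaf counts and so passed the filter only through the protoplast libraries, which fixed their direction. Lower loci outnumbered higher ones in other classes, with 20 and 10 of 36 tested microRNA loci (median -1.07), 53 and 17 of 93 loci typed only as noncoding RNA (median -0.68), and 12 and 5 of 20 small nucleolar RNA loci (median -1.22). The share of counts of the microRNA loci went the other way, from 0.0131% and 0.0125% in leaf to 0.0291% and 0.0275% in protoplasts. Of 6 transfer RNA loci 4 were lower and 0 higher. Apart from that of the mitochondrial loci, these medians kept their sign under every scaling tried.

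In the weighing of explanations that follows, the tests of scaling for the marker lists and for ethylene synthesis (its count of members was chosen after the interval of its median was seen), the intervals of list medians, and the tests of mesophyll share for stress lists and of cell loss for clock genes were chosen after the results were seen, as was the comparison of spreads within marker lists. Markers of epidermis, guard cell, xylem and phloem fell together. With the 5 scaling alternatives the falls stayed, with -3.508 as the highest median of the 5 lists, against -3.544 with TMM. Hardly any upward shift was among them, as the highest median of all genes was -0.006 (RLE factors), against -0.042 with TMM. As a scaling shifts all genes together, this outcome was nearly fixed in advance, and larger upward shifts were not tried. In the planned test of a lower share of these cell types, 3 of 87 called members were higher, a share of 0.0345. Its exact 95% interval of 0.717% to 9.75% treats members as independent, though they were measured in the same libraries. But a fall of these transcripts within cells that stayed in the preparation gives the same count. Nor did members of each list fall alike, with interquartile ranges of 0.907 to 3.38 on the log2 scale. This spread cannot separate a lower share from a fall within cells. For some lists it includes genes with 0 protoplast counts, whose fitted values depend on the prior count. For the epidermis, stripping off the lower side with tape lowers the share by design. How much of the falls a lower share accounts for was not tested.

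Stress and wounding lists rose. Leaving out the scaling factors did not account for 6 of the 7 called lists. Their lowest median with library size only was 2.0161, with every 95% bootstrap interval above 0. For ethylene synthesis the median was 2.791 with an interval over members of -0.636 to 7.81. Of its 6 members, 5 stayed called higher with library size only, which argues against this shift for this list too. A larger shift of all genes was not tested. A higher share of mesophyll RNA after the loss of other cells is argued against for most of the 7 called lists. This assumes that photosynthesis transcripts did not fall within mesophyll cells, which was not tested. For 5 of the 7 the median's interval lay above the log2 fold change of 1.72 of LHCB4.3, the highest of 65 photosynthesis genes. The intervals treat members as independent, and their lower ends were 1.77 for glutathione S-transferases and 1.71 for heat shock. Of 136 tested members of the 7 lists, 105 exceeded 1.72. These lists entered because they were called higher, which favours this outcome. The lists of salicylate defence and of abscisic acid and osmotic stress, not called as sets, did not enter. Their medians of 1.131 and 1.104 lay below 1.72, so for them this share is not argued against. A response to the tape, the enzymes, the osmoticum or the time in solution remains a hypothesis, and these steps cannot be separated in this design.

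Clock genes moved in opposite directions. If photosynthesis transcripts did not fall within mesophyll cells, the loss of other cells is argued against for the rises. Of the 8 clock genes that rose, 6 had a 95% interval wholly above the 1.72 of LHCB4.3. A later time of day at collection of the protoplasts stays possible. The 4 morning genes had a median of -0.68 and the 4 evening genes one of 3.2507. The test asked only for opposite signs, which these medians had, so a small morning fall was enough to pass it. It covered only these morning and evening genes of the 19 tested clock genes. The largest rise of the clock list, that of PRR5, and its largest fall lay outside the test. The log2 fold changes of the morning genes ran from -0.38 for LHY to -1.45 for PRR9. GI, with 0.32, rose little beside TOC1, with 4.77. A response of clock genes to the isolation itself at the same hour was not tested and stays open, since collection times are not given in the sources used here.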
